A study of Mus musculus with 4 samples.

How the data were processed

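Total RNA of 4 samples was labelled and hybridised to Illumina mouse bead arrays, 1 array for each combination of genotype and treatment. The submitters' processing notes name BeadStudio 3.2.3. The deposited signal of each probe is a linear intensity, and beside it the authors deposited a detection score for each probe, per the file headers. The detection p was taken as 1 minus that score. Per the file headers, the intensity column of the WT untreated array already holds normalized values, and it was identical to the authors' normalized values for that array (largest difference 0). The other 3 arrays were deposited before normalization. Their order of probes was nearly the same as in the authors' normalized values, with 0 reversals of neighbouring probes beyond a small tolerance. The Spearman correlations were 0.9999966 for WT IFNa, 0.9999968 for STAT3KO untreated and 0.9999959 for STAT3KO IFNa. The authors' normalization method is not given in the sources used here. The deposited intensities had medians of 75.0, 94.5, 96.7 and 77.4 in WT untreated, WT IFNa, STAT3KO untreated and STAT3KO IFNa. The authors' normalized values, on a linear scale without centring, had a median of 75.0 on each array. The brightness of the WT untreated array before normalization is not known.

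Signals were background-corrected with limma 3.58.1 in R 4.3.3 (normexp with background estimated from the detection p, offset 16), then quantile-normalized and taken to the log2 scale. The intensity distribution of the WT untreated array may already have been changed. Quantile normalization removes such a change only as far as the authors' step kept the order of probes. A probe was called detected at a detection p under 0.01. Of 46632 probes, 29976 had 1 gene symbol, 10 had several and 16646 had none in the platform table and stay unnamed here. Symbols were updated through the Entrez ID for 29921 probes and the accession for 12, with the RefSeq table of assembly GRCm38.p6, and 43 kept the platform's symbol. They named 17708 genes, 7571 of them with more than 1 probe. The probe with the highest mean log2 intensity over the 4 arrays stood for each gene. Of 572 entries in 27 gene lists, 524 matched a named gene. Isg15, Usp18 and Gbp2 are among the entries with no probe under that name, so nothing is reported on them. The result of 1 further list is not reported here.

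Differences of 2 arrays were computed over genes detected on at least 1 of the 2, and counted at 2-fold. The mean IFNa response and the mean genotype difference were tested with limma (genotype plus treatment, eBayes with an intensity trend, Benjamini-Hochberg over 10515 genes detected on at least 1 array), with 1 residual and 14.2 prior degrees of freedom. Where a probe was not detected on an array, its fold is a lower bound, written "at least": the brighter value against the higher of the lowest detected value on the dim array and the probe's own value. No fold is given where neither array detected it. Fitted mean differences of such genes are not bounds, and their size depends on the offset. A list is described by its median and by the percentile of that median among 10000 random lists of the same size, matched on mean intensity in 20 bins. The slope over the joined interferon lists was fitted by total least squares on responses centred on their means, with 10000 bootstrap draws of genes. Gene lists, tests and the rule for naming genes were fixed before the data were examined. The rule took Stat3, the 15 largest rises and 5 largest falls of the mean response among genes detected on at least 1 array and past 2-fold the same way in both genotypes (only 1 fall passed), the 10 largest differences of responses in each direction among genes detected on at least 2 arrays and past 2-fold in it, the 10 largest genotype differences in each direction among genes past 2-fold in both treatments and detected on at least 2 arrays, and, in each list, up to 4 detected members with the largest absolute value and any member needed by value to describe the list.

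The fit was tested on simulated arrays with the real genotype levels and a spread per intensity bin taken from the data, for the IFNa response over both genotypes (10515 genes). It called 46.0% of 50 genes changed 1.5-fold, 62.0% of 50 changed 2-fold, 98.0% of 50 changed 4-fold and all 50 changed 8-fold. It also called 23 unchanged genes, 13.1% of all 176 calls, and 19 of the 23 had a mean log2 intensity under 6.5. Of the real calls 3 lie under that intensity. The slope was recovered as 1.497 ± 0.047 (SD) where 1.5 was simulated over 72 genes with an assumed noise. No shift common to all genes was simulated. In the test of the fit each simulated response was the same in both genotypes, and all genes of an intensity bin had the same spread. The shares called therefore do not cover genes that respond unequally.

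Alternatives fixed in advance were no background correction, scaling to the 75th percentile, offset 50, the authors' normalized values, detection p under 0.05, detection on all arrays compared, no detection filter, thresholds of 1.5-fold and 3-fold, the mean of all probes, eBayes without trend, unmatched random lists and a ratio of medians in place of the slope. Bright genes only and cyclic loess were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.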

Results

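Gene expression was measured in mouse embryonic fibroblasts (MEFs), cultured connective-tissue cells derived from mouse embryos, of 2 genotypes: wild type (WT) and a knockout of Stat3 (STAT3KO), which encodes a transcription factor activated by cytokine receptors. Cells of each genotype were either left untreated or given IFNa, a type I interferon, at 1000 U per ml for 2 h. Each of the 4 groups was measured on 1 Illumina bead array, so there were no replicates, and the number of arrays limits the precision of every value. The arrays detected 16076 probes in WT untreated, 16814 in WT IFNa, 17524 in STAT3KO untreated and 16096 in STAT3KO IFNa, at a detection p under 0.01. A difference between 2 arrays is given as a value with no test. Only the mean IFNa response over both genotypes and the mean genotype difference over both treatments were tested, with limma. Those p-values rest on how far the response differs between the genotypes (1 residual degree of freedom) and mostly on the spread of other genes (14.2 prior degrees of freedom). They hold no spread between replicate samples. The labels do not say whether a genotype was more than 1 cell line.

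Stat3 itself was low in both arrays labelled STAT3KO. The brighter of its 2 probes had a normalized log2 intensity of 10.66 in WT untreated and 10.92 in WT IFNa, against 6.51 in STAT3KO untreated and 6.12 in STAT3KO IFNa. This was 17.7-fold lower without IFNa and 27.7-fold lower with it, and the limma test over both treatments gave an adjusted p of 1.34e-11. The other probe went from 10.36 to 6.36 and from 10.38 to 6.55 in the same comparisons. Both probes were still detected in STAT3KO, and the sources used here do not say which part of the gene was deleted or whether the probes lie within it.

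The first question was which genes respond to IFNa. Over both genotypes, 79 genes rose and 14 fell at an adjusted p under 0.05 (limma, 10515 genes), and 31 of them belong to 4 interferon lists fixed in advance, all 31 rising. The genes with the largest rise were Rsad2, which encodes the antiviral protein viperin, its neighbour Cmpk2, the immunity-related GTPases Irgm2, Igtp and Irgm1, the antiviral GTPase Mx2, the helicase Helz2 and Ifit3. Rsad2 was at least 44.4-fold higher with IFNa in WT and 191-fold higher in STAT3KO (limma adjusted p = 3.74e-11). Irgm1, detected on all 4 arrays, had log2 responses of 4.02 in WT and 4.32 in STAT3KO, with a mean of 4.17 ± 0.13 (limma SE, adjusted p = 3.59e-11). Cd274, which encodes the checkpoint ligand PD-L1, the chemokine Cxcl10, Samd9l, Parp14, Apol9b, Oasl1 and Stat2, a subunit of the interferon-activated factor ISGF3, made up the rest of the 15 largest rises. Of the 15, only Helz2, Irgm1, Cxcl10 and Samd9l were detected on both untreated arrays, so the order depends partly on values at background. Cxcl10 went from 8.73 to 12.10 in WT and from 6.56 to 11.37 in STAT3KO on the log2 scale. Selenbp1, a selenium-binding protein gene, was the only gene at least 2-fold lower with IFNa in both genotypes (mean log2 response -1.20 ± 0.24, limma adjusted p = 0.023). Its other detected probe gave -0.59 in WT and a mean of -0.86. No gene was 2-fold lower in both genotypes with no background correction, offset 50, the authors' values, the mean of all probes, detection on all arrays or bright genes only.

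By list, 12 of 21 detected antiviral effectors rose and none fell (limma over all genes), or 18 adjusted over the list alone. Eif2ak2, the kinase PKR, rose, with log2 responses of 2.90 in WT and 2.91 in STAT3KO. Of the 23 genes of nucleic acid sensing and interferon signalling, 10 rose (18 adjusted over the list alone), among them Irf9 with log2 responses of 3.49 and 3.28, Irf7 with 1.78 and 3.22, and Trex1 with 1.99 and 2.55. All 8 detected interferon-inducible GTPases were higher on average, 5 past the limma test over all genes and 8 adjusted over the list alone. Antigen presentation had the lowest median response of these 4 lists, 0.35 (log2): 4 of 20 genes rose (6 adjusted over the list alone), and those 4 were Psmb8, Psmb10, H2-T22 and Nlrc5. A second probe of H2-T22 had a mean log2 response of -0.05. Psmb8, an immunoproteasome subunit, had log2 responses of 1.16 and 1.33. B2m was 0.23 and 0.31 higher without passing the test. Among chemokines and cytokines 4 of 23 rose, which were Cxcl10, Il6, Il15 and Csf1, and 1 fell adjusted over the list alone. Among the negative regulators of JAK-STAT signalling Socs1 alone of 16 passed the test (log2 responses 0.50 and 1.74, adjusted p = 0.022). Stat2 and Irf9 alone of the 13 receptor and JAK-STAT components passed it. Among the STAT3 targets Zfp36, which encodes an mRNA-destabilizing protein, rose and Lcn2, a lipocalin, fell (1 and 2 adjusted over the list alone). Among immediate-early genes Zfp36 rose and Gadd45a fell (1 and 2 adjusted over the list alone), and among NF-kB targets Il6 rose and Lcn2 fell. Lcn2 was also the epithelial marker that fell (2 adjusted over the list alone). No gene of the fibroblast, remaining cell type, extracellular matrix, Hox, housekeeping, cell cycle or p53 lists passed the limma test of the IFNa response, adjusted over all genes or over the list alone. No heat shock gene passed it over all genes, and 3 were lower adjusted over the list alone. Hypoxia and glycolysis genes had a median log2 response of -0.32, below all 10000 matched random lists, with Ndrg1 and Ankrd37 falling (4 lower adjusted over the list alone).

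The additive limma fit takes a gene's own part of the spread from how far the response differs between the genotypes, so it disfavours genes that respond unequally. Without the intensity trend in the variance no gene passed after adjustment, and 284 of 10515 had an unadjusted p under 0.05, against 439 with the trend, both fewer than the 5% that chance gives, and with the mean of all probes 11 genes passed.

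In WT alone, 93 genes were at least 2-fold higher and 28 lower with IFNa among 9716 genes detected on either array. In STAT3KO alone, 127 were higher and 74 lower among 9904. The arrays of these comparisons are separate, and 52 genes were higher and 1 lower in both, where independent lists would share 0.925 and 0.0835. The split of higher against lower depended on the scaling. In WT it was 40 and 3 with no background correction, 104 and 144 with scaling to the 75th percentile, and 37 and 4 with the authors' normalized values. In STAT3KO it was 77 and 5, 355 and 44, and 68 and 4 in the same order, and 120 and 115 with cyclic loess.

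The question the crossed design poses is whether the response differs without STAT3. Among 72 detected genes of the 4 joined interferon lists, the median response was 0.60 in WT and 1.60 in STAT3KO on the log2 scale, or 1.51-fold and 3.04-fold. With undetected values at their bounds these medians were 0.64 over 60 genes and 1.31 over 70. The response was larger in STAT3KO for 58 of the 72. Among the 41 detected on all 4 arrays it was larger for 35, or 85.4%, against 44.5% of the 8088 other genes detected on all arrays. The median difference of responses was 0.50 over all 72 genes and 0.49 over those 41, and the first lay above all 10000 random lists matched on intensity. In the antiviral list the median difference was 1.19, in sensing and signalling 0.56, in the GTPases 0.80 and in antigen presentation 0.19. Some members were at background. Over the 8, 7, 2 and 10 members detected on all arrays with a mean log2 intensity of at least 8, the medians were 0.61, 0.27, 0.80 and 0.34. The value of 0.19 for antigen presentation changed sign to -0.11 with scaling to the 75th percentile, a setting under which the median over all genes was -0.43, against -0.06 in the reported setting.

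**Figure D1:**
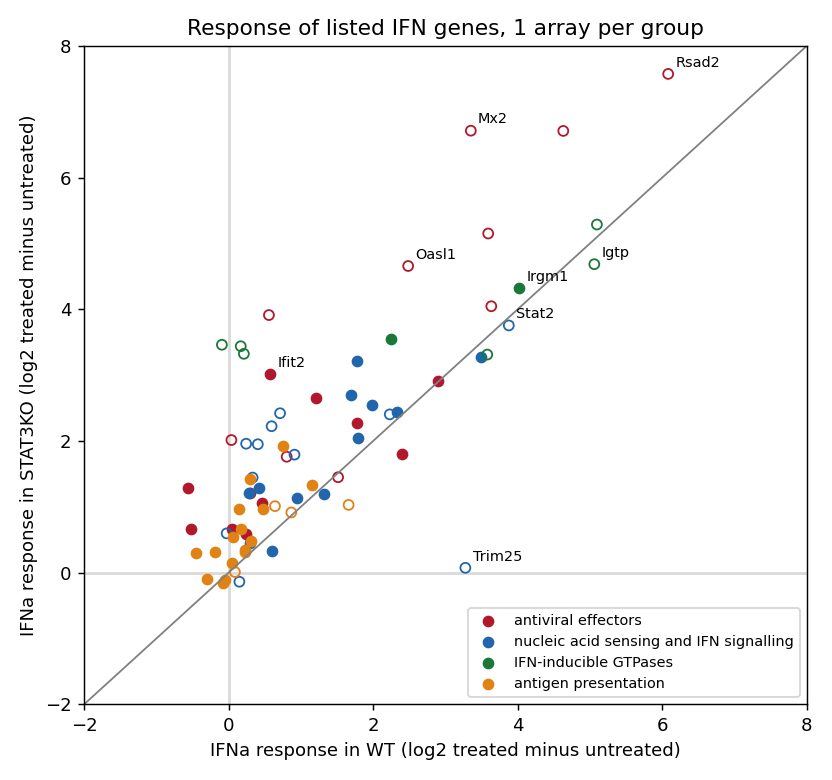
Log2 response to IFNa in WT (x axis) against STAT3KO (y axis) for the 72 detected genes of the 4 interferon lists, 1 array per group. Filled points are genes detected on all 4 arrays, open points are detected on fewer, and the line marks equal responses; 58 genes lie above it, and Trim25 lies far below.

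Single genes of the response differed to unlike extents. For Irf9, Irgm1, Helz2 and Eif2ak2, detected on all arrays, the differences of responses ranged from -0.43 for Helz2 to 0.30 for Irgm1 on the log2 scale. Ifit2, an RNA-binding antiviral effector detected on all arrays, was 1.49-fold higher with IFNa in WT and 8.11-fold higher in STAT3KO, and Clec2d was 2.86-fold and 12.6-fold higher. Part of both differences lay in a lower untreated level. STAT3KO minus WT (log2) was -1.07 for Ifit2 and -1.16 for Clec2d without IFNa, and 1.37 and 0.98 with it. Mx2 was at least 4.99-fold higher in WT and at least 99.7-fold higher in STAT3KO. Oas1g, an oligoadenylate synthetase gene, was at least 1.11-fold and at least 12.0-fold higher (the lowest difference of responses among its 3 detected probes was 0.67, against 3.36 on the probe used), Oasl1 5.59-fold and at least 15.5-fold, and Trim30a at least 1.67-fold and 11.8-fold. Gbp2b, a guanylate-binding protein gene, was not detected in WT with or without IFNa, and was 11.0-fold higher with IFNa in STAT3KO. Bst2, the virion-tethering protein tetherin, had log2 responses of 1.21 and 2.66, but its level was lower in STAT3KO than in WT both without and with IFNa. Without IFNa, Oasl1 was at least 1.42-fold lower in STAT3KO than in WT, and Trim30a at least 1.40-fold higher. In the other direction Trim25, a ubiquitin ligase acting in RNA sensing, was 9.68-fold higher with IFNa in WT and was detected on neither STAT3KO array. The other 9 genes with the largest negative difference (Olfr44, Taf6l, Nudt7, Efcab2, Mblac1, Sorcs2, Odf3, Rtn2 and Phyhipl) were dim, reaching at most a log2 intensity of 7.21, in Nudt7, and Gdpd4, Phf11d and Olfr744 complete the 10 largest positive ones.

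The total least squares slope of the STAT3KO response on the WT response was 1.17 over the 72 genes, with a 95% bootstrap interval of 0.99 to 1.40 that covers the spread between genes only. The ratio of the median responses was 2.68. The slope is fitted on centred responses, so a shift common to the 72 genes is left out of it and enters the ratio. Over all 10515 genes the median difference of responses was -0.06. NF-kB targets had a median difference of -0.54 and chemokines and cytokines one of -0.51, both below all 10000 matched random lists. The lists share Ccl2, Ccl5, Ccl7, Cxcl1, Cxcl2, Cxcl5 and Il6, so they are not separate results. The members went both ways: 5 of 27 NF-kB targets and 9 of 23 chemokines and cytokines had a positive difference, and of the latter 5 were at least 2-fold towards STAT3KO, with Cxcl10 at 1.44 and Tnfsf10 at 1.88, and 2 towards WT. For Cxcl10, STAT3KO minus WT was -2.18 without IFNa and -0.73 with it (log2), so its level with IFNa was not higher in STAT3KO. Ccl20 (log2 responses 0.56 in WT and -0.89 in STAT3KO), Cxcl1 (0.10 and -0.72), Ccl7 (0.67 and -0.26) and Bcl3 (0.75 and -0.63) were among those with a negative difference. The medians of STAT3 targets and of immediate-early genes differed between responses by -0.18 and 0.05, within the middle 95% of random lists. The housekeeping list had a median difference of 0.32 and the cell cycle list one of 0.15, at percentiles 99.98 and 99.82 of random lists, and these stand beside the interferon lists as measured. The cell cycle value was -0.37 with scaling to the 75th percentile.

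Over all 10515 genes, 662 had a difference of responses of at least 2-fold towards STAT3KO and 338 towards WT. Of 10315 genes simulated with no IFNa response and with the spread of these differences, 679 were past 2-fold. Because that spread came from the measured differences themselves, this number is not an independent count for noise. The measured counts rested mostly on dim probes. Of the 5335 bright genes (detected on all arrays with a mean log2 intensity of at least 8) 0.90% were past 2-fold, against 18.4% of the others. The split was 59 and 13 with no background correction, 50 and 17 with the authors' values, 965 and 740 with scaling to the 75th percentile, 478 and 454 with cyclic loess, and 39 and 9 among bright genes. The difference of responses has no residual degrees of freedom and no test. It adds WT untreated and STAT3KO IFNa and subtracts WT IFNa and STAT3KO untreated. The added arrays detected fewer probes (16076 and 16096) than the subtracted ones (16814 and 17524). Before normalization STAT3KO IFNa was also dimmer than the subtracted arrays, while the brightness of WT untreated is not known. Shifts that depend on the scaling therefore cannot be told apart from an effect of genotype on the response.

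**Figure D2:**
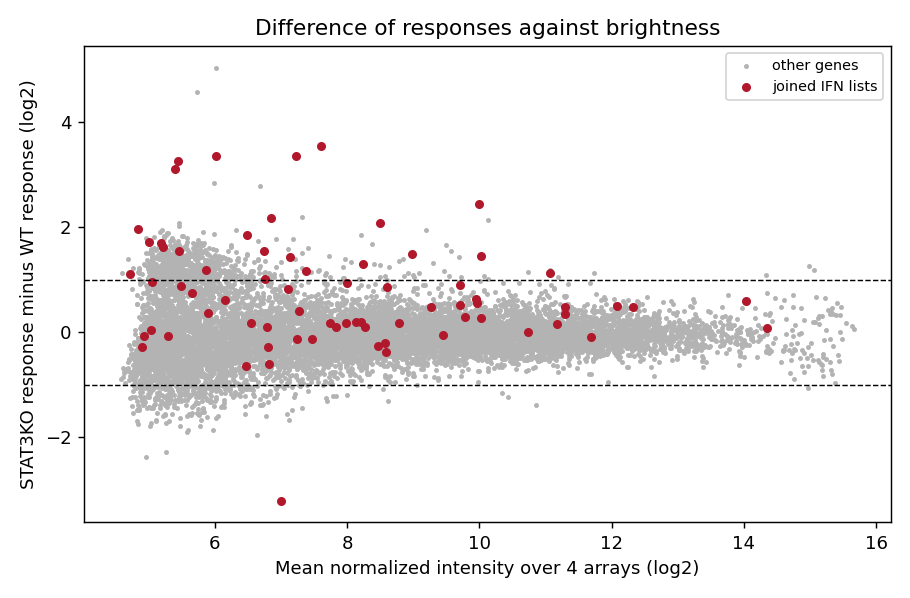
Difference of IFNa responses (STAT3KO minus WT, log2; y axis) against the mean normalized log2 intensity over 4 arrays (x axis) for the 10515 genes tested, 1 point per gene; red points are the joined interferon lists and dashed lines mark 2-fold. The spread of the other genes is widest at low intensity, and 4 of the 27 bright interferon genes are past 2-fold towards STAT3KO.

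The lines differed far more from each other than either did with IFNa. STAT3KO exceeded WT by at least 2-fold for 1255 genes and was lower for 990 without IFNa (10214 genes), and the counts were 1016 and 1059 with IFNa (10023 genes). In both treatments 831 genes were higher and 773 lower, where independent lists would share 122 and 103. The limma test over both treatments called 2368 genes higher and 2044 lower in STAT3KO among 10515. Across the 8129 genes detected on all arrays, the log2 intensities of the WT arrays correlated with each other at r = 0.99, as did the STAT3KO arrays, while WT untreated and STAT3KO untreated correlated at r = 0.92, a value across genes, which are not independent replicates.

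Connective-tissue genes were lower in STAT3KO in most cases. Of 30 detected extracellular matrix genes, 29 were lower in STAT3KO and 1, Mmp9, higher (limma, over all genes and adjusted over the list alone), with a median log2 difference of -2.97. Fbln2 was at least 278-fold lower without IFNa, and Thbs2 at least 107-fold lower. Bgn, Timp3 and Lox, an enzyme that cross-links collagen, were at -6.68, -6.30 and -5.33 on the log2 scale. With undetected values at their bounds the list median was -2.64 without IFNa and -2.60 with it. Of 14 fibroblast markers 9 were lower and none higher. The listed markers Col1a1, Col1a2, Col3a1, Dcn, Lum and Fn1 also belong to the extracellular matrix list, so these counts overlap. Thy1, a surface glycoprotein of fibroblasts, was 13.90 and 14.15 in WT and not detected in STAT3KO, at least 429-fold lower without IFNa (limma adjusted p = 3.28e-16). Pdgfra and Twist2 were at -4.10 and -4.15 (a second probe of Pdgfra was at 0.01), while Vim, the intermediate filament of mesenchymal cells, was -0.02 (adjusted p = 0.945) and Twist1 -0.19 (adjusted p = 0.261). Hox genes, which mark position along the body axis, were split: 15 of 22 were lower and 4 higher in STAT3KO. Hoxc6, Hoxc8 and Hoxc9 were at 12.40, 11.62 and 11.45 in WT untreated and not detected in STAT3KO on the probes used, while a second detected probe was at 0.12 for Hoxc6 and -0.10 for Hoxc8 in the mean genotype difference, and Hoxa11, Hoxa7, Hoxa5 and Hoxa9 were the 4 higher ones. Hoxa11 was not detected in WT and stood at 9.70 and 9.38 in STAT3KO. With bounds the Hox median was -2.39 without IFNa and -2.30 with it.

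Among 28 detected STAT3 targets, 18 were lower and 3 higher in STAT3KO (19 and 3 adjusted over the list alone). The acute-phase genes Hp and Saa3 were at least 148-fold and 103-fold lower without IFNa, the cytokine receptor gene Osmr at least 44.0-fold lower (a second probe of Hp was at -2.19 on the log2 scale), and Socs3, a feedback inhibitor of cytokine signalling, fell by 2.32. Icam1, Tnfrsf1a and Mcl1 were the higher members. Stat3 is itself in that list and fell by 4.47. Immediate-early genes had 17 of 25 lower and 3 higher, with a median of -1.39: Ccn2, Ccn1 and Jun were at -4.12, -4.08 and -3.22, and Egr2 was at least 13.4-fold lower without IFNa. NF-kB targets went both ways, 12 lower and 10 higher (13 and 10 adjusted over the list alone), with Cxcl5 28.0-fold lower without IFNa and Cxcl1 2.23 higher (log2). Chemokines and cytokines likewise had 11 lower and 8 higher; Il33 was 21.4-fold lower without IFNa, Cxcl12 was at -3.91 (a second probe at -0.85), and Ccl20 was 2.96 higher.

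Of the 72 genes of the joined interferon lists, 33 were higher and 9 lower in STAT3KO (limma, over all genes and adjusted over the lists alone). All 8 detected GTPases passed the limma test, with a median log2 difference of 2.24, or 1.82 without and 2.68 with IFNa with undetected values at their bounds. Gbp3 was 8.61 without IFNa in STAT3KO and not detected in WT. Of the sensing and signalling genes 11 were higher and 1, Trim25, lower. Irf8 was at least 7.53-fold higher with IFNa, and Irf5 and Irf1 were 2.60 and 1.72 higher on the log2 scale. Of the antiviral effectors 9 were higher, and Bst2 alone was lower, at -1.95. Antigen presentation had 5 higher and 7 lower, with H2-T22 at -1.72 and Psme2 at 1.31. Over the joined lists the median STAT3KO minus WT value was 0.14 without IFNa, within the middle 95% of random lists, and 1.12 with IFNa, above all 10000.

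The 10 genes highest in STAT3KO relative to WT were Arap3, Hspb8, Blnk, Tgm2, Scx, Tusc1, Mgmt, Csn3, Cyth4 and Trim54, by the fitted mean on the probe used for each. In 7 of them that probe was detected on neither WT array, so their order depends on values at background. Second probes gave a mean log2 difference of 0.81 for Arap3 and 0.36 for Cyth4, whose probes used were at least 80.2-fold and at least 41.7-fold higher without IFNa, and 3.15 for Blnk (6.38 on the probe used). Hspb8, a small heat shock protein gene, was 83.5-fold and 87.9-fold higher without and with IFNa, and Tgm2, a transglutaminase gene, at least 54.9-fold and at least 49.2-fold. Scx, a tendon transcription factor gene, was at least 70.0-fold higher without IFNa and 72.5-fold with it. Beside Thy1, Fbln2, Hoxc6, Hoxc8, Thbs2, Hp and Saa3, the 10 lowest by the fitted mean included Dlk1, Slpi and Crabp1, and 8 of the 10 were detected on neither STAT3KO array. Dlk1 was at least 285-fold lower without IFNa, where its other detected probe gave a log2 difference of -4.70. Ptpn6, the phosphatase SHP-1, was at least 20.9-fold higher in STAT3KO without IFNa. Of the negative regulators 3 were higher and 5 lower, and of the receptor and JAK-STAT components 3 and 3. In the cell cycle list 11 of 26 genes were higher and none lower, with Foxm1 at 1.29 (0.33 on a second probe) and Cdc20 at 0.97.

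The lists of markers of other cell types were short. Of 4 detected skeletal muscle markers 2 were higher and 1 lower, of 6 epithelial ones 1 and 2, of 7 endothelial ones 1 and 1 (0 and 1 adjusted over the list alone), of 3 macrophage and leukocyte ones 1 and 0, and of 6 neural ones 1 and 2. Smooth muscle markers had 0 higher and 3 lower of 7, and cartilage, bone and fat markers 0 higher and 4 lower of 8. The median of the last was -0.83, at percentile 0.22 of random lists, and that of skeletal muscle markers was 0.66, at percentile 93.99. Tnni1, a slow skeletal muscle troponin gene, was at least 5.82-fold higher without IFNa, and Laptm5, a leukocyte gene, at least 3.58-fold higher. Heat shock and unfolded protein response genes had 2 higher and 10 lower of 17, p53 pathway genes 3 and 3 of 11, hypoxia and glycolysis genes 4 and 8 of 20, and housekeeping genes 1 and 4 of 15. With 1 possible line per genotype, STAT3 loss and any other difference between the lines fall together in every genotype comparison.

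**Figure D3:**
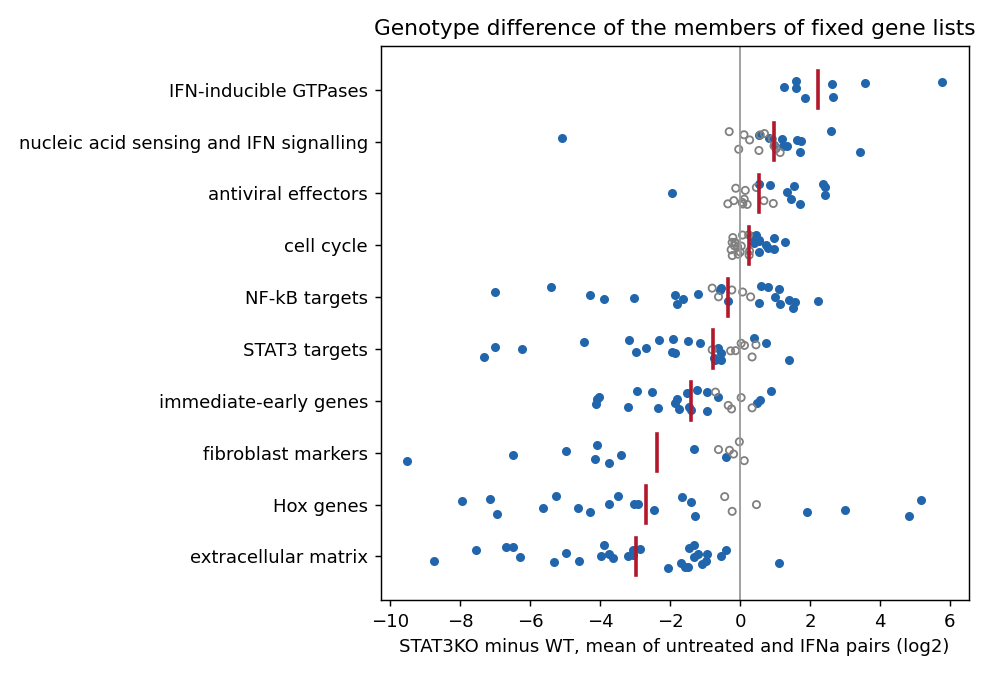
Genotype difference (STAT3KO minus WT, mean of the untreated and IFNa pairs, log2; x axis) of the detected members of 10 fixed gene lists, 1 point per gene. Blue points passed the limma test at an adjusted p under 0.05, open points did not, and red lines are list medians, from 2.24 for the GTPases to -2.97 for extracellular matrix.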

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

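All tests weighed in this part were chosen after the result was seen. The one on genes between Trim25 and Stat3 was fixed before its own counts were made, but after Trim25 had been picked by its value.

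A difference between groups picked out 1 gene, Gdpd4, whose response was past 2-fold in opposite directions: it was 2.15-fold lower with IFNa in WT and 2.14-fold higher in STAT3KO. The difference was not tested, and the number of genes that independent lists would share in opposite directions was not computed. No gene was past 2-fold in opposite directions with no background correction, offset 50, the authors' values or among bright genes, nor any past 3-fold, while 42 were with scaling to the 75th percentile. A signal in data outside the comparisons picked out 24 probes without a gene name that were at least 2-fold higher with IFNa in both genotypes, where independent lists would share 0.416 of 3832 such probes detected in both genotypes.

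The first pattern is the number of genes past 2-fold in the difference of responses. Dim probes could account for most of it: 0.90% of bright genes were past 2-fold against 18.4% of the others, and 952 of the 1000 genes were not bright. A shift shared by genes of like brightness does not account for the share of bright interferon genes past 2-fold. It was 14.8% (4 of 27, exact 95% interval 4.19 to 33.7%) towards STAT3KO, against 0.66% of other bright genes. That test covers only genes past 2-fold, and its interval treats genes measured on the same 4 arrays as independent. The median difference of bright genes was 0.61 in antiviral effectors, 0.80 in GTPases, 0.27 in sensing and signalling and 0.34 in antigen presentation. It was 0.32 in the housekeeping control and -0.05 over all bright genes. The last 2 interferon lists are thus not set apart from the control. Those 4, named after their values were seen, are Bst2, Ifi47, Ifit2 and Psmb10. With IFNa the level of Bst2 was still lower in STAT3KO than in WT. A larger response without STAT3, a larger response of this line for another reason and a departure of the single sample in a group all stay open. The number of probes detected per array runs together with this difference. A contribution from it was not tested beyond the shift weighed above.

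The second pattern is the low extracellular matrix expression of STAT3KO. Noise of single arrays is argued against, since 29 of 30 members were lower in both the untreated and the treated pair, which share no array. A difference between the lines that does not come from STAT3, such as the embryo region or the passage history, cannot be told apart from loss of STAT3: 19 of 22 detected Hox genes differed between the lines, and each genotype may be 1 line.

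The third pattern is the Trim25 probe, which had no signal in STAT3KO. A failed hybridisation of a whole STAT3KO array is argued against, since at least 34.5% of probes were detected on the STAT3KO arrays, as on the WT arrays, and Trim25 was undetected on both STAT3KO arrays. Trim25 and Stat3 both lie on chromosome 11. A differing chromosome segment around Stat3, carried along with the knockout, may contribute: 9.68% of the 124 tested genes between Trim25 and Stat3 were past 2-fold lower in STAT3KO in both treatments, against 7.29% of the 10383 other genes (one-sided Fisher's exact p = 0.196), and 14 of the 124 were past 2-fold higher against 12 lower, which does not decide it. A fault of this probe and a sequence difference under it were not tested.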

How the results depend on the processing

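Bright genes only and cyclic loess were chosen after the data were seen, and all other alternatives before. No paired analysis was possible because each group had 1 array, and leaving out an array would leave 0 residual degrees of freedom in the additive limma fit. Of the alternative values of the main results, 96 stayed within 1.5 times the reported count, slope or fold. For counts this was judged on the total alone, and the split into higher and lower could turn. The other 62 follow, and where no construction explains the change the cause was not tested.

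Genes at least 2-fold changed with IFNa numbered 121 in WT and 201 in STAT3KO. They were 43 and 82 with no background correction, 248 and 399 with scaling to the 75th percentile, 55 and 95 with offset 50, 41 and 72 with the authors' values, 54 and 112 with detection on all arrays compared, and 26 and 49 among bright genes. A threshold of 1.5-fold gave 920 and 1125, and 3-fold gave 41 and 71. Changed in both were 53 genes, against 33 with the authors' values, 30 with detection on all arrays, 95 at 1.5-fold, 34 at 3-fold and 22 among bright genes.

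Genes that differed between genotypes numbered 2245 without and 2075 with IFNa. They were 1385 and 1353 with no background correction, 1263 and 1206 with the authors' values, 4686 and 4195 at 1.5-fold, 1018 and 1007 at 3-fold, and 921 and 864 among bright genes. Those in both treatments numbered 1604, against 981 with the authors' values, 1027 with detection on all arrays, 2932 at 1.5-fold, 814 at 3-fold and 691 among bright genes. Their split, 831 higher and 773 lower, was 542 and 550 with no background correction, 678 and 686 with scaling to the 75th percentile, and 557 and 470 with detection on all arrays. With IFNa the split of 1016 and 1059 was 915 and 1321 with that scaling and 755 and 634 with detection on all arrays. The limma split was 752 and 751 with that scaling.

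The difference of responses was past 2-fold for 1000 genes. This was 72 with no background correction, 1705 with scaling to the 75th percentile, 137 with offset 50, 67 with the authors' values, 401 with detection on all arrays, 2313 at 1.5-fold, 111 at 3-fold, 604 with the mean of all probes and 48 among bright genes. The limma test of the IFNa response called 93 genes, against 149 with no background correction, 46 with scaling to the 75th percentile, 141 with offset 50, 147 with the authors' values, 55 with no detection filter, 11 with the mean of all probes, 30 among bright genes, 143 with cyclic loess and 0 without the trend, where 284 had an unadjusted p under 0.05, against 439 with it, both fewer than the 5% of 10515 genes that chance gives. The limma test of the genotype called 4412, against 1503 with scaling to the 75th percentile, 2922 with the mean of all probes, 2933 among bright genes and 2631 without the trend. Fewer genes are tested among bright genes and with detection on all arrays.

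The median STAT3KO response of the joined interferon lists was 0.91 with the authors' values, and the ratio of the medians was 2.68 in place of a slope of 1.17. By construction the slope leaves out a shift common to the genes of these lists and the ratio carries it, so they measure different things. The Stat3 check (mean genotype difference of Stat3, log2) gave -3.69 with no background correction and -3.40 with the authors' values, against -4.47. The median difference of responses of the joined lists stayed positive in every alternative run.

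With scaling to the 75th percentile the median response over all genes was 0.30 in WT, -0.12 in STAT3KO and -0.43 in their difference, and the last was -0.13 with cyclic loess, against 0.02, -0.03 and -0.06 in the reported setting. Of the list medians outside the middle 95% of random lists, 5 changed sign with scaling to the 75th percentile. These were the IFNa response of extracellular matrix (0.014) and of cartilage, bone and fat markers (0.032), and the difference of responses of antigen presentation (-0.11), cell cycle (-0.37) and smooth muscle markers (-0.35). The genotype median of chemokines and cytokines was 0.082 with no detection filter, and that of Hox genes was 3.91 among bright genes, where few members are left. Some medians within the middle 95% also changed sign, as that of receptor and JAK-STAT components in the IFNa response did among bright genes. Over all list medians, 247 values of the IFNa response, 253 of the difference and 222 of the genotype stayed within 1.5-fold, and 9, 2 and 34 moved. Of the named genes, 41 values of rises with IFNa moved and 87 did not, and the 8 values of the fall did not. For the difference of responses, 19 values moved and 66 did not towards STAT3KO, and 32 and 49 towards WT. For the genotype, 36 moved and 48 did not among the genes higher in STAT3KO, and 33 and 49 among the lower.

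Signal over background limits the single-pair values: 16076 to 17524 of 46632 probes were detected, and the dim ones carry most of the differences of responses.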

Other observations

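Xist, the RNA that silences an X chromosome, was detected on all arrays, at log2 intensities of 8.94 and 8.60 in WT and 10.38 and 9.94 in STAT3KO. Of the Y-linked genes in the list only Uty was detected on any array, at 5.44, 5.47, 5.51 and 4.89 in the order WT untreated, WT IFNa, STAT3KO untreated and STAT3KO IFNa (undetected on the last), close to the lowest detected values of 5.37, 5.26, 5.16 and 5.37.

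The cyclin-dependent kinase inhibitor genes Cdkn2c and Cdkn2b were 3.07 and 1.07 higher in STAT3KO, Cdkn1a was -1.16, and Cdkn2a was 0.17 (limma adjusted p = 0.299). Car9, a hypoxia-induced carbonic anhydrase gene, was not detected in WT and stood at 8.29 and 7.19 in STAT3KO (a second probe had a mean genotype difference of 0.20), while the hypoxia gene Vegfa fell by 2.68, and Adm was 8.36-fold lower without IFNa. These genes were chosen after their values were seen.

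Among the probes without a gene name, 3 of the 5 with the largest mean response were detected on all arrays, with log2 responses of 2.77, 3.68 and 3.36 in WT and 5.87, 3.89 and 3.46 in STAT3KO, in the same order. The other 2 were not detected in WT untreated and had log2 responses of 6.43 and 3.43 in STAT3KO.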
